A study of Caenorhabditis elegans with 4 samples.

How the data were processed

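Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where NHR-23, a nuclear hormone receptor of Caenorhabditis elegans known for its role in molting, sat on DNA in L2 larvae. The worms carried a transgene that encodes NHR-23 fused to GFP and a FLAG tag, together with a rescuing copy of unc-119, in the strain OP43. Per the labels' protocols, synchronized animals were grown at 20 °C on HB101 bacteria, crosslinked with formaldehyde and sonicated, and the tagged protein was recovered with affinity-purified goat antibodies against GFP. Part of each chromatin extract was kept aside as input DNA. The labels give 4 samples, 2 ChIP and 2 input, and the groups and replicate numbers were taken from the sample titles. The labels do not say whether the replicates came from separate cultures.

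Peak lists for ChIP replicate 1, ChIP replicate 2 and a combined list were analysed, 3 lists in all. Per the file headers, coordinates are on WormBase WS180, and each line names PeakSeq, a caller that scores a ChIP library against its input, as the source. The deposited values are q-values, 1 per peak, which the authors wrote both as the score and as the attribute of each peak. The q-value is therefore the peak's own value from the authors' caller, and it was used only to rank, describe or filter peaks. Each replicate list belongs to 1 ChIP library. How the combined list was made, the aligner, the caller's settings and thresholds, and the read depth are not given in the sources used here. The precision of a peak call therefore could not be expressed in reads. The inputs can enter only through the peak calling and had no list of their own in the data analysed.

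Every list was checked for peaks that overlap within the list, and none did. Peaks from 2 lists were counted as shared when they overlapped by at least 1 bp. The share of replicate 1 peaks shared with replicate 2 was compared with 10000 random placements of the replicate 1 peaks on their own chromosomes, between the first base and the highest coordinate in any list, because chromosome lengths of WS180 were not used here. The p-value is one-sided, and the smallest these placements can give is 0.0001. Relations between q-values of shared peaks were tested by 100000 permutations, as was the difference in median rank between shared and unshared replicate 2 peaks; the smallest p these can give is 1e-05. Ranks run from 1 for the smallest q-value, with ties at their mean rank. Paired widths and q-values were compared with exact two-sided sign tests, and shares carry exact (Clopper-Pearson) 95% intervals that cover counting error only. With 1 list per replicate, p-values compare peaks with random placements or with other peaks, not worms with worms.

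The counting in the overlap test was checked on simulated data before use, for replicate 1 against replicate 2. In 100 simulations of 48 peaks with 20 planted overlaps, a mean of 20 planted overlaps was recovered, with a mean of 0.26 chance overlaps among the rest. Of 1000 unrelated lists, 4.8% gave p under 0.05. The planted peaks were copies of replicate 2 peaks shifted by less than their width, so their recovery was fixed in advance. The unrelated lists were placed at random in the same way as the placements they were compared with. Both checks therefore cover the counting only, not how the test treats peaks that cluster. The calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and the plots matplotlib 3.10.9.

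The tests, the alternatives and the regions to be named were fixed before the data were examined, apart from the sign tests, the rank classes, the width comparisons, the binomial tests over chromosomes and their parts, and the alternatives added later. The Pearson correlations and the rank test of replicate 1 peaks missing from replicate 2 were not in the plan either. The added alternatives are the placement within 100 kb, replicate 2 at the highest replicate 1 q-value, the combined list against each replicate list alone, the rank correlation without the 2 farthest regions and over replicate 1 q-values above 1e-08, and all alternatives for the middle parts of chromosomes and for the spacing of peaks. The regions named are the 10 combined peaks with the smallest q-values and the 15 replicate 1 peaks with the smallest q-values among those that overlap a replicate 2 peak. The genes nhr-23 and unc-119, which the transgene carries, were also to be named. The gene table used here is on the assembly WBcel235, a different build from that of the peaks, so no peak was assigned to a gene. For the same reason the planned location of peaks relative to gene starts, the search for the AGGTCA receptor half-site and the tests of 15 fixed gene lists (cuticle collagens, molting and apical matrix, hedgehog-related, astacin peptidases, nuclear hormone receptors, heterochronic and molting-cycle regulators, epidermis and seam regulators, markers of intestine, muscle, pharynx, neurons and germ line, ribosomal proteins, histones and small noncoding RNAs) were not carried out. The test of the X share against gene share had been planned for a matching build only. It was made all the same after seeing the data, as part of the chromosome tests, because it uses gene numbers per chromosome and no positions, and the span reached by the lists stood in for chromosome length. From the gene table, only the number of protein-coding genes per chromosome and the chromosome of the 2 transgene genes were used. Some rows of the deposited lists may not have been among those analysed here.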

Results

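Binding of GFP-tagged NHR-23 in L2 larvae was mapped in 2 ChIP libraries, with 2 input DNA samples as controls. No ChIP from worms without the tagged protein was among the samples, so which peaks are specific to NHR-23 was not tested. NHR-23 is the worm ortholog of the ROR nuclear receptors and acts in the larval molts. The list of ChIP replicate 1 held 48 peaks, that of replicate 2 held 918 peaks and the combined list 928 peaks. The replicate 1 peaks had a median width of 343.5 bp and covered 27356 bp. The replicate 2 peaks had a median width of 239 bp and covered 267967 bp, and the combined peaks had a median width of 236 bp and covered 272483 bp. The q-values, which are the authors', ran from 4.42e-39 to 1.96e-05 in replicate 1, and from 1.08e-98 to 0.000113 in both replicate 2 and the combined list. Read depth per library is unknown from the files, so no value here carries an error in reads. All positions are on WormBase WS180. The gene table used here places nhr-23 on chromosome I and unc-119 on chromosome III, but on another build, so neither locus was compared with the peaks.

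By q-value, the strongest region of all 3 lists was a broad domain on chromosome IV. In the combined list it ran from 9606815 to 9620288, 13474 bp, with a q-value of 1.08e-98. Replicate 1 called the part from 9611619 to 9620108, also as its first peak (q = 4.42e-39). This region was 57.1 times as wide as the median combined peak and held 4.94% of the covered length of the combined list, and its replicate 1 part held 31% of the covered length of that list. The combined peaks ranked second to sixth were also called in replicate 1. They lay on V from 14506668 to 14507590 (q = 1.19e-45), on I from 8985737 to 8986370 (q = 2.87e-42), on V from 19427929 to 19430717 (q = 2.42e-32), on IV from 1911171 to 1911807 (q = 4.13e-31) and on V from 15660945 to 15661393 (q = 9.11e-29). In replicate 1 these regions had q-values of 3.62e-16, 5.81e-11, 1.21e-11, 1.02e-10 and 4.82e-11, at ranks 3, 6, 4, 7 and 5 of 48.

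The other 4 of the first 10 combined peaks lay further down the replicate 1 list or were missing from it. The peak on IV from 14032720 to 14034311 had q = 3.64e-27 in the combined list and 1.5e-05 in replicate 1, where it ranked 42. The peaks on V from 9274131 to 9274836 and from 5425001 to 5425437 had combined q-values of 9.11e-20 and 3.78e-19, and ranked 30 and 24 in replicate 1. The peak on X from 12171888 to 12173028 (q = 1.46e-20) had no replicate 1 peak. Of these first 10 combined peaks, 5 lay on chromosome V and 3 on chromosome IV.

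**Figure D1:**
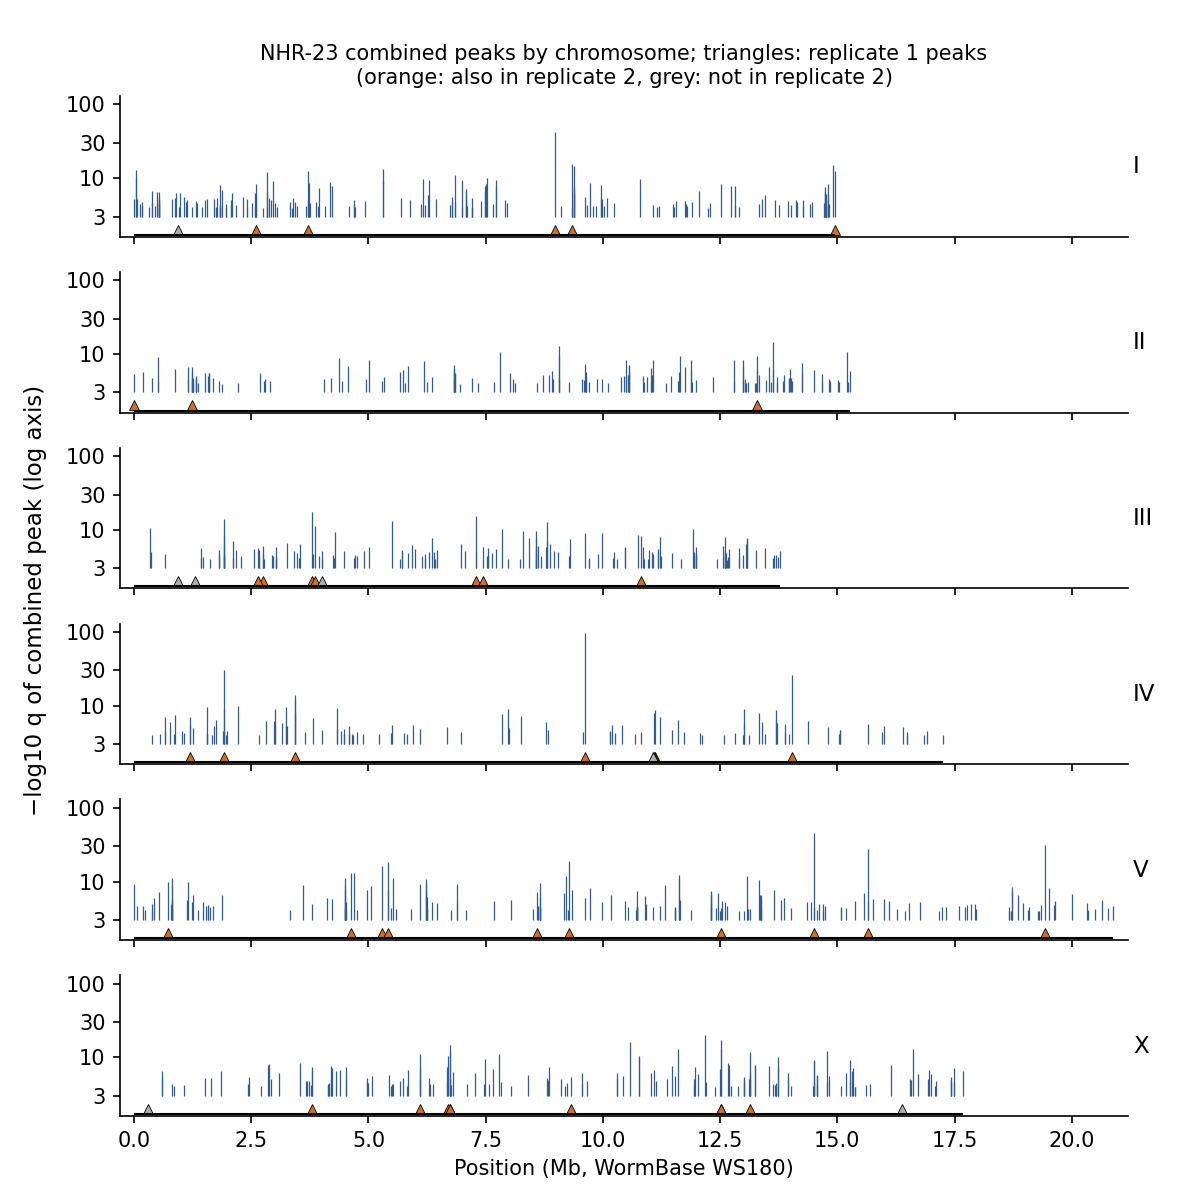
Combined NHR-23 peaks along the 6 chromosomes. The x axis is the position in Mb on WormBase WS180 and the y axis is −log10 of the authors' q-value on a log scale, with a line for each of the 928 combined peaks. Triangles mark the 48 replicate 1 peaks, orange for the 41 that overlap a replicate 2 peak and grey for the 7 that do not. The tallest line is the domain on IV from 9606815 to 9620288.

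The replicates were compared to ask whether they marked the same regions. Of the 48 replicate 1 peaks, 41 overlapped a replicate 2 peak, which is 85.4% (95% interval 72.2 to 93.9%). Random placement gave a mean of 0.358 overlapping peaks and at most 4, so the observed number was 115 times the mean (placement permutation p = 0.0001, one-sided, the smallest it can give). Placing the peaks only within 100 kb of where they lay, an alternative added after seeing the data, gave a mean of 1.79 and at most 7 (placement permutation p = 0.0001). Seen from the longer list, the same 41 regions were 4.47% of the replicate 2 peaks (95% interval 3.22 to 6.01%), and 877 replicate 2 peaks had no replicate 1 counterpart.

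Beyond the 6 regions ranked first in the combined list, the rule for named regions picks 9 further replicate 1 peaks that overlap replicate 2. Both peaks on V among these had the smaller q-value in replicate 1. The one from 5284005 to 5285300 had q = 2.46e-20 (rank 2) in replicate 1 and 6.41e-17 (rank 13) in replicate 2. Those on X from 12511309 to 12511761, on III from 7300107 to 7300531, on I from 9332565 to 9332839 and on III from 3797169 to 3797491 ranked 12, 16, 15 and 11 in replicate 2. The peaks on I from 14948537 to 14948841 and on IV from 3439407 to 3440065 ranked 34 and 23 there. The peak on IV from 1199779 to 1200016 ranked 190. The one on V from 12509903 to 12510295 had q = 4.06e-07 (rank 18) in replicate 1 and 4.1e-05 (rank 668 of 918) in replicate 2.

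Peaks found in both replicates were concentrated among the strongest of replicate 2. Their median rank was 35 of 918, against 479.5 for the 877 replicate 2 peaks without a counterpart, a difference of -444.5 ranks (permutation p = 1e-05, two-sided, the smallest it can give). Their median q-value was 4.9e-13 and their median width 439 bp, against 1.09e-05 and 228 bp for the others. Among the first 25 replicate 2 peaks, 17 were also in replicate 1 (68%, 95% interval 46.5 to 85.1%). The count was 7 of the next 25 (28%, interval 12.1 to 49.4%), 1 of the 50 at ranks 51 to 100, 8 of the 100 at ranks 101 to 200, 7 of the 200 at ranks 201 to 400, and 1 of the 518 peaks from rank 401 on (0.193%, interval 0.00489 to 1.07%).

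**Figure D2:**
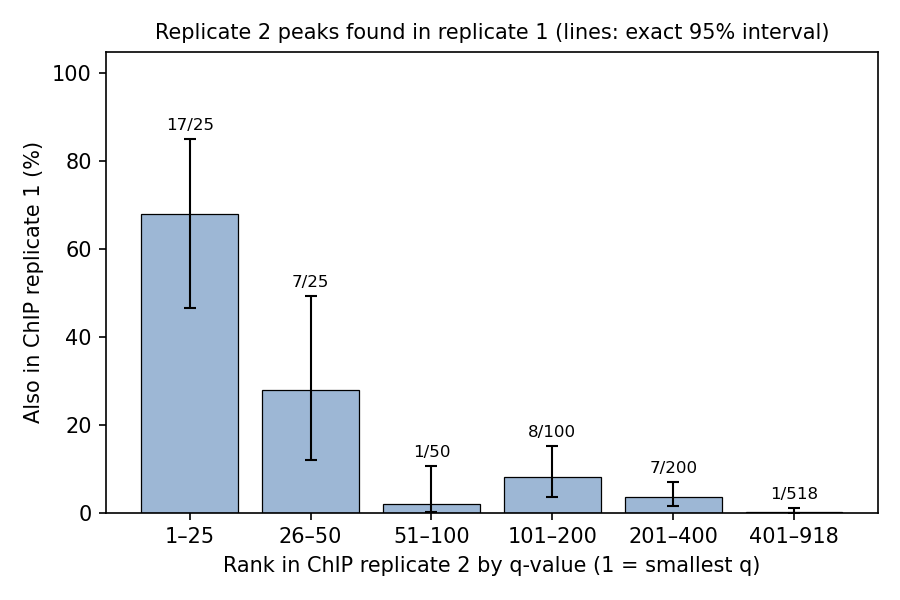
Share of replicate 2 peaks that overlap a replicate 1 peak, by rank in replicate 2. The x axis gives the ranks by q-value, rank 1 being the smallest, and the y axis the share in percent. Bars are shares with the counts above them, and error lines are exact 95% binomial intervals; the share is 68% at ranks 1 to 25 and 0.193% at ranks 401 to 918.

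At the 41 shared regions the replicate 2 calls mostly had smaller q-values and wider intervals. The replicate 2 q-value was smaller in 37 of 41 regions (exact sign test p = 1.03e-07), and the replicate 2 interval was wider in 34 of 41 (exact sign test p = 2.53e-05). Both tests count regions of 1 pair of libraries, and read depth is unknown, so they cannot tell depth from enrichment. The median ratio of widths, replicate 2 over replicate 1, was 1.33 (quartiles 1.11 and 1.7), and 33 of the 41 replicate 1 intervals lay inside their replicate 2 interval. The 4 regions with the smaller q-value in replicate 1 were those on V starting at 5284005 and at 12509903 in replicate 1, on III at 7446779 and on X at 9324982. Across the 41 regions, −log10 q-values of the replicates were related, with a Spearman rho of 0.566 (permutation p = 0.00016, adjusted 0.00016 over 2 relations) and a Pearson r of 0.884 (permutation p = 3e-05, adjusted 6e-05). These are relations across regions, which are not independent replicates. Without the 2 regions farthest from the replicate 1 median, rho was 0.518 (permutation p = 0.00085) and r was 0.842 (permutation p = 1e-05). Over the 34 regions with replicate 1 q-values above 1e-08, rho was 0.274 (permutation p = 0.116) and r was 0.238 (permutation p = 0.177). That split was made after seeing the data and narrows the range of q-values, which itself lowers a correlation.

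**Figure D3:**
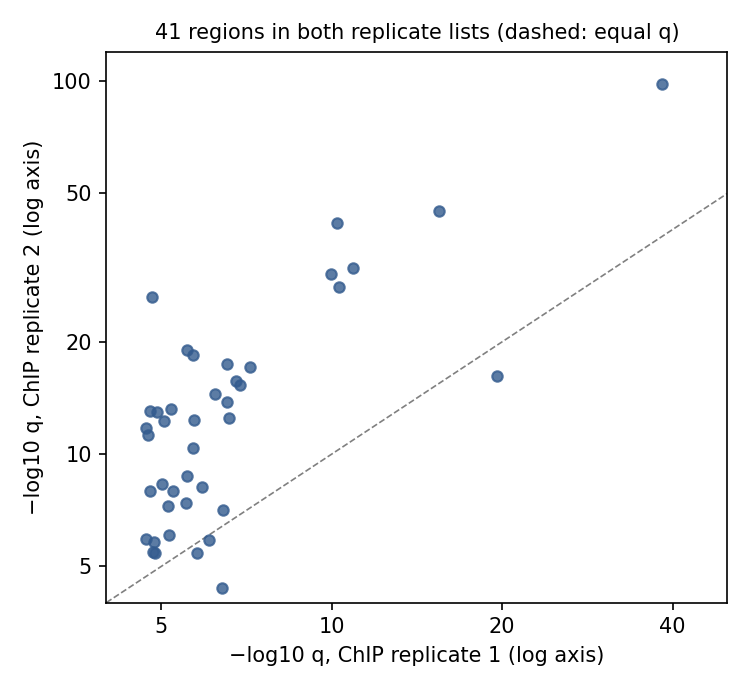
The authors' q-values at the 41 regions in both replicate lists. The x axis is −log10 q in ChIP replicate 1 and the y axis −log10 q in ChIP replicate 2, both on log scales, and each point is a region. The dashed line marks equal q-values; 37 points lie above it, and the point at the upper right is the domain on IV.

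The 7 replicate 1 peaks without a replicate 2 counterpart were spread through that list. Their median rank was 26 of 48, against 24 for the 41 shared peaks (permutation p = 0.913, two-sided). They lay on IV from 11070896 to 11071282 (q = 5.05e-08, rank 8), on III from 1299607 to 1300472 (rank 11), from 931226 to 931823 (rank 13) and from 4016676 to 4016726 (rank 45), on X from 293241 to 293627 (rank 26) and from 16370200 to 16370569 (rank 27), and on I from 933314 to 933711 (rank 28). Those 7 fall outside the rule for named regions and were chosen after their values were seen. The nearest replicate 2 peak lay between 11539 and 299518 bp away. None of the 7 overlapped a combined peak, although a combined peak lay 41 bp from the one on III at 4016676.

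The combined list was close to the replicate 2 list. A replicate 2 peak overlapped 883 of the 928 combined peaks, which is 95.2% (95% interval 93.6 to 96.4%), and a replicate 1 peak overlapped 41 of them, or 4.42% (interval 3.19 to 5.95%). All 41 of these also overlapped replicate 2. In 689 of the 883 pairs (78%) the combined q-value equalled that of replicate 2 in every digit, and 598 pairs also had the same start and end. The first 10 combined peaks all carried the replicate 2 q-value. In the 194 pairs whose q-values differed, the median difference was 0.22 on the log10 scale, and the combined value was the larger one in 90. The 45 combined peaks found in neither replicate ranked 388 or lower, with a median rank of 803 and a median width of 95 bp. The 35 replicate 2 peaks left out of the combined list had a median rank of 762 and a median width of 97 bp.

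Combined peaks were spread over all 6 chromosomes. Chromosome I held 184 peaks, which is 12.3 per Mb of the span reached by the lists, III held 147 (10.7 per Mb), II held 144 (9.43 per Mb), V held 181 (8.67 per Mb) and IV held 12.1% of the list (6.49 per Mb). Chromosome X held 160 peaks, which is 17.2% of the list (95% interval 14.9 to 19.8%) and 9.05 per Mb. In replicate 2 the X share was 17.9%, and in replicate 1 it was 22.9% (11 of 48 peaks, interval 12 to 37.3%). With the span of each chromosome cut into left, middle and right parts of equal length, 327 combined peaks lay in the left parts, 271 in the middle parts and 330 in the right parts. The left part held the most peaks on chromosomes I (85, against 48 and 51) and IV (53, against 25 and 34), and the right part the most on X (69, against 44 and 47), II (65, against 38 and 41) and III (55, against 45 and 47). On V the parts held 62, 63 and 56. The middle share of 29.2% was below a uniform spread (exact binomial p = 0.00733), but among the 464 combined peaks with the smaller q-values it was 33.4% (exact binomial p = 1). These tests count each peak as independent, which neighbouring peaks are not, so the smaller p-value is likely too small.

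Wider combined peaks tended to have smaller q-values, with a Spearman rho of 0.571 between width and −log10 q across the 928 peaks (permutation p = 0.0001, the smallest that its 10000 permutations can give). Width and q-value come from the same peak call, so they are not independent measures of binding. There were 123 combined peaks under 50 bp (13.3%), including 6 of 1 bp, and 121 such peaks in replicate 2. Replicate 1 had none, its narrowest peak being 51 bp. Of the 13 combined peaks over 1000 bp, 5 were also in replicate 1. The widest after the domain on IV were on III from 13778103 to 13781227 (3125 bp, rank 419) and on V from 18721752 to 18724670 (2919 bp, rank 113), and neither was in replicate 1.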

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

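No paired analysis was possible because the ChIP and input samples that share replicate numbers were not both represented by peak lists analysed here. The overlap of replicate 1 with replicate 2 kept its direction and its side of the threshold under 4 planned and 2 added alternatives. The share was 83.3% with an overlap of at least 50% of the shorter peak, 75% with midpoints within 200 bp, 83.3% against the better 459 replicate 2 peaks and 87.5% for the better 24 replicate 1 peaks. The share of combined peaks found in a replicate list rose to 99.4% for the better 464 combined peaks, where 3 of the 45 peaks found in neither replicate remain. Leaving out a replicate, an alternative added later, gave 4.42 to 95.2%, the lower value without replicate 2, so that share rests on replicate 2. The rank correlation fell from 0.566 to 0.274 (permutation p = 0.116) over the 34 regions with replicate 1 q above 1e-08, a split added later that narrows the range, and was 0.518 without the 2 regions farthest from the replicate 1 median, also added later. The share of peaks on X was 20.5% among the better 464 combined peaks, and 17.9 to 22.9% when the list of the remaining replicate replaced the combined list; the cause was not tested. With alternatives added later, the middle share of the chromosomes moved from 29.2% to 33.4% among the same 464 peaks, to the other side of a uniform spread, and was 29.3 to 33.3% when a replicate was left out, the upper value resting on 16 of 48 peaks in replicate 1 (exact binomial p = 1); the cause was not tested. Ranking by score in place of q-value gave no separate value because the files hold the same number for both. The expected X share was taken from the span reached by the lists, not from chromosome lengths as planned. Not run, for want of a matching build, were all alternatives for gene starts, the half-site and the gene lists. With 48 peaks and no read depth, the absence of a region from the replicate 1 list shows only that it was not called there.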

Other observations

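In this part, the spacing tests of the combined list were set out before their results were seen, and the spacing in other lists and the tests on the replicate lists, the combined q-values and the chromosome counts were chosen after the results were seen. The densest stretches of NHR-23 peaks were short runs of several peaks each. Taking combined peaks less than 10 kb apart as a run, 17 runs held 4 or more peaks, 77 peaks in all (8.3%), while 590 peaks (63.6%) stood alone. The longest run by number was on II from 6821081 to 6844809 with 6 peaks, the strongest at rank 187. A run on III from 1921031 to 1927168 held 5 peaks in 6138 bp, the strongest at rank 21, and a run on I from 9375323 to 9383079 held 4, the strongest at rank 18. Only the runs on II from 1229264 to 1247324 and on X from 6737427 to 6750381, among these 17, included replicate 1 peaks (1 and 2). On V, 3 of the 13 combined peaks over 1000 bp lay together between 18710760 and 18724670, at ranks 871, 184 and 113. In the first 10 kb of the chromosomes there were 3 combined peaks, on I from 3757, on II from 131 and on V from 8695, against 0.558 for a uniform spread. The one on II was also in replicate 1. The opposite ends of the chromosomes were not counted, and the difference from a uniform spread was not tested.

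The chromosomes differed in how many peaks they held, and a hypothesis that peaks follow the number of protein-coding genes or the length of the chromosomes was tested. A chi-square test over the 6 chromosomes used counts simulated from the expected shares. Its simulation p was 1e-05 against gene numbers, the smallest it can give, and 2e-05 against the spans. Counting each run under 10 kb once (725 regions), the same chi-square test gave simulation p = 1e-05 and 0.00055. Chromosome I held 19.8% of peaks, above its 14.4% of genes (exact binomial test, adjusted p = 8.11e-05 over 12 tests) and its 15% of the span (exact, adjusted p = 0.000237). The replicate 2 share on I was 19.6%, while replicate 1 had 12.5% there (6 of 48 peaks, 95% interval 4.73 to 25.2%). Chromosome IV held 12.1%, below its 16.4% of genes (exact, adjusted p = 0.000554) and 17.3% of the span (exact, adjusted p = 8.14e-05). Replicate 2 had 12.1% of its peaks on IV, and replicate 1 16.7% (8 of 48, interval 7.48 to 30.2%), and on both chromosomes the wide replicate 1 interval holds the gene share and the span share. The combined list is nearly that of replicate 2. For X the answer depends on the yardstick: 17.2% of peaks against 13.7% of genes (exact, adjusted p = 0.00438) but 17.7% of the span (exact, adjusted p = 0.797). Chromosome V was below its gene share (19.5% against 25%, exact, adjusted p = 0.000237), with 20.9% of the span (exact, adjusted p = 0.376). Chromosome III held 15.8%, against 13.2% of genes (exact, adjusted p = 0.0388) and 13.8% of the span (exact, adjusted p = 0.117), and II held 15.5%, against 17.3% of genes (exact, adjusted p = 0.22) and 15.3% of the span (exact, adjusted p = 0.855). Neighbouring peaks are not independent, gene numbers come from a later build, and no biological explanation was tested.

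The contrast between 48 peaks in replicate 1 and 918 in replicate 2 was weighed first. A stricter q-value limit for replicate 1 is argued against as the whole cause, since 557 replicate 2 peaks passed the highest replicate 1 q-value. Lower sequencing depth or enrichment in replicate 1 stays open for the 877 replicate 2 peaks without a counterpart. The shared peaks had a median rank at 3.81% of the replicate 2 list, but that value was known before the explanation was put to it, depth was not analysed, and a weaker signal in the worms would look alike. It would leave the 7 replicate 1 peaks missing from replicate 2 without an account, and 0 of the 7 lay within 500 bp of a replicate 2 peak, which argues against a shifted interval beside a replicate 2 peak. No biological explanation was tested, as the labels give both libraries the same strain and stage.

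A second pattern is the agreement of the combined q-values with those of replicate 2. If the combined q-values had been computed from the pooled reads of both libraries, they would differ where replicate 1 itself had a peak. In 34 of 41 such regions the combined q-value was that of replicate 2 to every digit, including the domain on IV where replicate 1 alone gave q = 4.42e-39, which argues against pooled reads as the origin of these values. The combined value was smaller in 2 of the remaining 7 regions and larger in 5. Among the pairs without a replicate 1 peak, 655 of 842 kept the replicate 2 q-value (77.8%), against 82.9% of those with one. The combined list was not a plain copy of replicate 2, since 45 of its peaks overlapped neither replicate and 194 of 883 pairs differed in q-value. None of the 7 replicate 1 peaks missing from replicate 2 overlapped a combined peak. The one on III at 4016676 had a combined peak 41 bp away, and its nearest replicate 2 peak was 72390 bp away. How the list was made stays open, and so does whether a peak's presence in it carries any information from replicate 1.

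The third pattern is the closeness of combined peaks. Neighbours under 500 bp apart numbered 21, against a mean of 4.35 in 1000 random placements (permutation p = 0.001, the smallest they can give), and neighbours 500 to 2000 bp apart numbered 65 against 13.1 (permutation p = 0.001). Under 500 bp there were 22 such pairs in the replicate 2 list and 9 among the better 464 combined peaks (permutation p = 0.001 each), and 0 in the short replicate 1 list. A single wide bound region split by the caller may account for the shortest gaps. Neighbours 2000 to 10000 bp apart were also 1.76 times as many as placed at random (117 against 66.5, permutation p = 0.001). That excess cannot decide whether splitting is the whole cause. The widest combined peak spanned 13474 bp, so a split region of that size could leave such gaps too. Variation in density at the scale of 500 kb is argued against as the whole cause, since peaks moved by up to 500 kb left the observed number under 500 bp 4.45 times higher (permutation p = 0.001). Clustering of bound genes at finer scale was not tested and stays open.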
